A study of Gordonia sp. KTR9 with 6 samples.

How the data were processed

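Gene expression was measured on 1-colour oligonucleotide arrays in Gordonia sp. KTR9, a soil actinobacterium that degrades the explosive RDX with enzymes encoded on the plasmid pGKT2, and in a derivative cured of that plasmid. Per the labels, 3 separate cultures of each strain were grown in LB, a rich medium, at 30 °C and 180 rpm for about 48 h, to late logarithmic or early stationary phase, and 1 array was hybridised per culture with Cy3-labelled cRNA. The labels' protocols name a DNase step during RNA extraction.

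Per the file headers, Agilent Feature Extraction 10.7.3.1 gave the deposited spot intensity values, with the local background subtracted and spatial trends removed within each array and low values replaced by a small positive surrogate. No scaling between arrays had been applied to them. A table of the whole series held 5246 values per array, 1 per gene, which the values show to be on a log2 scale. Its rank correlation with the scanner signals across genes rounded to 0.999 or more on each array, its array medians lay between 5.83 and 5.86, and 5 of its 6 columns reached the same maximum of 19.6. How the authors made these log2 values, and whether they were centred, is not given in the sources used here, and they served only as an alternative.

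Each array held 15208 non-control spots for 5364 probes, most of them with 3 spots, and 77 negative control spots. The probes covered 5246 genes, of which 5179 had 1 probe, 16 had 2 and 51 had 3. Spots marked as non-uniform or as population outliers were left out, and no spot was saturated. The log2 processed signals of a probe's spots were averaged, and the 75th percentile of the array's non-control probes was subtracted. A probe was kept where more than a share of 0.5 of its spots was well above background on at least 3 of the 6 arrays, which kept 5361 probes. Kept probes of a gene were averaged, and 5243 genes were tested. None of the 67 genes with several kept probes had probes called in opposite directions. Strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all 6 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Run medians per array were compared with exact permutation tests in scipy 1.17.1, where 3 arrays against 3 cannot give a p below 0.1. The number of arrays limits the precision.

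For a gene not well above background on any cured array, only a bound is given. It sets the mean of the wild-type arrays against the mean over the cured arrays of the higher of 2 values, the lowest signal of a probe well above background and the gene's own signal, as normalized log2 values. The bound therefore holds for this normalization only. Values were simulated from the means and spreads of the 5243 genes. Of 100 genes moved by 1 on the log2 scale, 79% were recovered, and of 100 moved by 0.5, 28% were. There were 6 false calls. Noise was drawn independently for each gene, with no shift shared by the genes of an array. These figures therefore do not carry over to the measured arrays, where such a shift was seen.

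The groups, the test, the filter, the thresholds and most alternatives were fixed before the data were examined. The planned comparison set pGKT2 against the rest of the genome. The files give locus tags without gene names, products or replicons, and no annotation was used here, so pGKT2 membership, the planned gene lists and the planned shift of the other plasmids were not analysed here. In their place, runs of neighbouring locus tags were defined after the data were seen. A running median over 7 genes was taken of the difference between strains minus that of the median gene. Genes at -2 or below were marked low and those at 0.9 or above high, stretches needed at least 4 genes, gaps of up to 5 genes were closed, and a run needed at least 20 genes. The 3 runs found, and 3 short low or high stretches among the last locus tags, were set apart from the remaining genes, called outside genes. A short low stretch elsewhere, of 5 genes, was left among the outside genes.

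The rule for named genes took the largest rises and falls among outside genes that passed the test and whose 3 cured and 3 wild-type values did not overlap. Because the files do not pair locus tags with names, only the first 2 in each direction are printed, and stretches of genes are given by their locus tag numbers. The alternatives covered scaling, background correction, the filter, the summary of probes, the variance model, the slide, the replicate number, each replicate left out, and the series table. Slide 1 held wild-type replicate 2, slide 2 held cured replicates 1 and 3, and slide 3 held cured replicate 2 with wild-type replicates 1 and 3. Values from slide 3 therefore rest on 1 cured array, which is assumed to vary like the 2 wild-type arrays, the only source of the spread. A fixed slide block takes its strain difference from the same 3 arrays and is no separate check.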

Results

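Transcript signals of 5246 genes were measured in 3 cultures of wild-type Gordonia sp. KTR9 and in 3 cultures of the strain cured of pGKT2. The question was how expression in LB differs without the plasmid. Between 95.4% and 95.9% of the non-control spots were well above background on the cured arrays, and between 98.97% and 99.9% on the wild-type arrays. Before scaling, the median signal was 162, 110 and 168 on cured arrays 1 to 3 and 47.9, 52.3 and 75.3 on wild-type arrays 1 to 3. Rank correlations across probes of the genes outside the 3 runs described next, which are not independent replicates, were 0.957 to 0.987 between cured arrays, 0.980 to 0.993 between wild-type arrays and 0.883 to 0.956 between strains.

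Signal was lost or lower in the cured strain over 2 separate runs of neighbouring genes. Run 1 spanned the locus tags numbered 5 to 800, and all of its 152 genes were lower in the cured strain. Run 2 spanned the locus tags numbered 25090 to 25565, and all of its 91 genes were lower. These are counts from limma at an adjusted p of 0.05, and both runs were chosen after the data were seen. The median signal of run 1 before scaling was 1.96 ± 0.167 (SD, n = 3) on the cured arrays and 106 ± 26.3 (SD, n = 3) on the wild-type arrays. For run 2 it was 2.87 ± 0.539 (SD, n = 3) and 108 ± 24.9 (SD, n = 3). Negative control spots had a median of 1.58 ± 0.158 (SD, n = 3) on the cured arrays and 1.37 ± 0.295 (SD, n = 3) on the wild-type arrays.

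In run 1, 126 of the 152 genes were well above background on every wild-type array and on no cured array. Their lower bounds had a median of at least 30.9-fold lower, with a range from 8.98 to 5516. In run 2 this held for 63 of the 91 genes, with a median bound of at least 30.3-fold lower and a range from 6.05 to 2896. No outside gene was lost in this way. These bounds hold only for the percentile scaling over all non-control probes and were not computed under the others. The median log2 difference of run 1 was -6.38 with that scaling, -5.61 with spike-in scaling and -6.75 with median scaling. For run 2 it was -5.71, -4.95 and -6.08. Both alternatives shift whole arrays, so the bounds would be lower with spike-in scaling and higher with median scaling. In each run, 14 genes stayed well above background on all 3 cured arrays, and all 14 of each were lower in the cured strain. Their median difference was -3.69 on the log2 scale in run 1, which is 12.9-fold lower, and -3.26 in run 2, which is 9.56-fold lower. These differences ranged from -6.33 to -1.25 in run 1 and from -6.66 to -0.76 in run 2. A further 12 genes of run 1 and 14 of run 2 were well above background on some but not all cured arrays. The longest unbroken stretch of genes below the low threshold held 124 neighbours, against at most 5 in 1000 shuffled gene orders. Shuffled orders treat neighbours as independent. On slide 3, the only slide with both strains, all 152 and all 91 genes were lower, from 1 cured array against 2 wild-type arrays whose spread alone entered the test. A fixed slide block, which takes its strain difference from the same 3 arrays, gave 151 and 91.

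**Figure D1:**
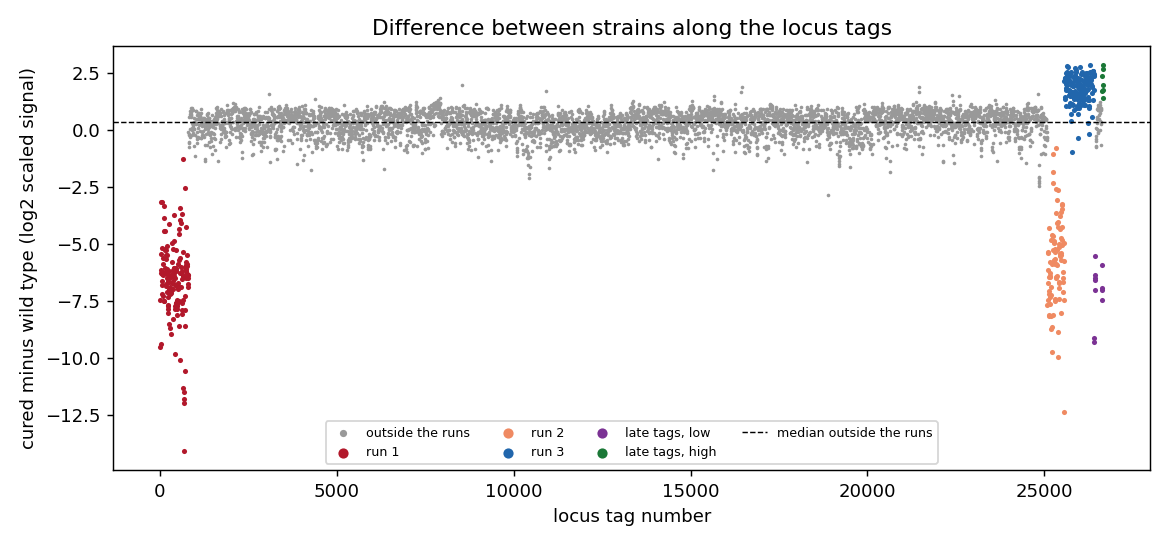
Difference between strains per gene (cured minus wild type, log2 scaled signal; y axis) against locus tag number (x axis), 1 point per gene, coloured by run and by the short low and high stretches of the last locus tags, with a dashed line at the median of the outside genes, 0.37. Runs 1 and 2 lie far below the line and run 3 lies above it; genes not well above background are drawn at their measured values.

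Another run rose over most of its genes. Run 3 followed run 2 directly, from locus tag number 25570 to 26410, and 153 of its 158 genes were higher in the cured strain, 2 were lower and 3 did not pass the limma test. Its median signal before scaling was 149.7 ± 31.9 (SD, n = 3) on the cured arrays and 18.1 ± 3.29 (SD, n = 3) on the wild-type arrays. The outside genes had median signals of 153 ± 32.8 (SD, n = 3) and 57.3 ± 14.4 (SD, n = 3). After scaling, the median difference of run 3 was 1.96 on the log2 scale, against 0.37 for the outside genes. The longest unbroken stretch of genes above the high threshold held 19 neighbours, against at most 4 in 1000 shuffled gene orders, which treat neighbours as independent. The rise of run 3 was thus more broken than the loss, whose longest stretch held 124.

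All 158 genes of run 3 were well above background on every cured array and 138 of them on every wild-type array. Relative to the outside median of the same array, the run 3 median was -0.033 ± 0.023 (SD, n = 3) in the cured strain and -1.65 ± 0.10 (SD, n = 3) in the wild type. The change was 1.62 on the log2 scale, or 3.06-fold. Its exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. Run 3 was chosen by its rise on these same arrays, so the test is no separate support for that rise. The median rise of run 3 over that of the outside genes, 1.60 on the log2 scale, was 1.59 on slide 3, from its 1 cured array, and a fixed slide block gives that same value by construction. With normexp background correction, which also added an offset of 50 to the signals, it was 0.62. Such an offset shrinks log2 differences between weak signals, and run 3 had a median processed signal of 18.1 on the wild-type arrays. The value therefore does not show the effect of background correction alone.

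**Figure D2:**
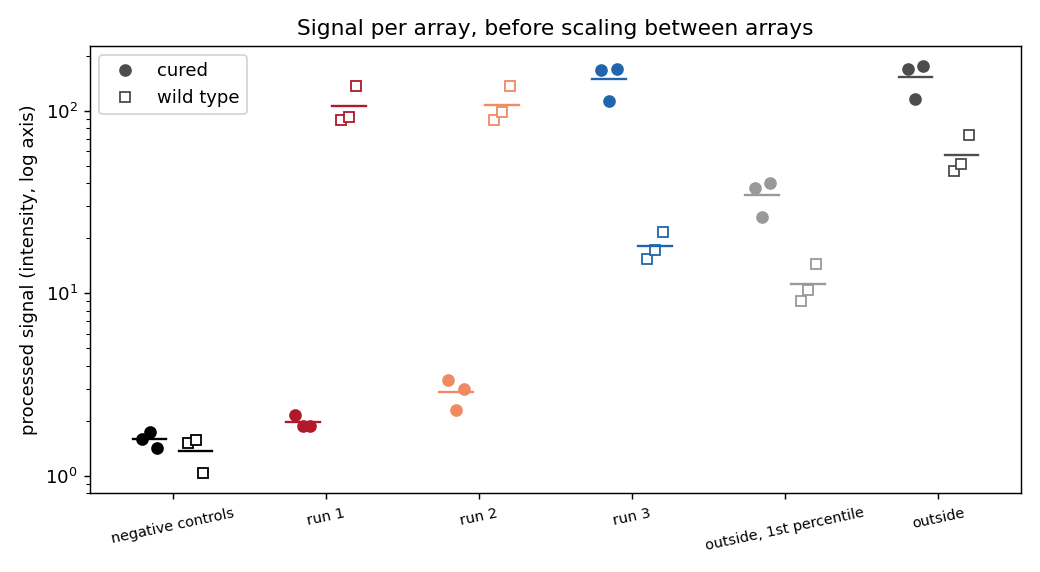
Processed signal before scaling between arrays (intensity, log axis) for each array, as the median of the negative controls, runs 1 to 3 and the outside genes, and as the 1st percentile of the outside genes; filled circles are the 3 cured arrays, open squares the 3 wild-type arrays and bars the means. On the cured arrays, runs 1 and 2 have medians of 1.86 to 3.35, near the negative controls, and run 3 has medians of 113 to 168.

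Among 4824 outside genes tested, 2610 were higher and 560 lower in the cured strain by limma at an adjusted p of 0.05. Of these, 199 rose and 78 fell at least 2-fold, a balance that turned to 7 and 264 with median scaling and to 81 and 96 with the 75th percentile taken without the lost runs. With spike-in scaling 2868 rose and 9 fell, and with normexp 7 and 29. On slide 3 alone, with its 1 cured array, 39 rose and 34 fell at least 2-fold, and with slide as a random block 70 and 51. The outside genes as a whole had a median difference of 0.37 on the log2 scale. The strains' values did not overlap for 3415 genes, or 70.8%, and for 3117 genes, or 64.6%, with median scaling. That scaling removes a shift shared by all genes of an array, but not a difference that depends on signal level. Chance gives 10% only where no difference is shared by all genes of an array, so that share is not the no-change value here.

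The balance of rises and falls changed with the scaling. Higher calls made up 82.3% of calls, but 53.3% with median scaling (1412 higher, 1239 lower) and 99.2% with spike-in scaling (4104 and 34). With normexp, which changed the signal, the background correction and the offset together, they made up 59.0% (658 and 458). The median outside difference was 0.00, 1.14 and 0.07 on the log2 scale in these 3 settings and 0.14 with quantile normalization, which gave 1648 and 598. On slide 3 alone, 1281 genes were higher and 179 lower, with 1 cured array and the spread taken from 2 wild-type arrays; a fixed slide block, with the same strain differences, gave 1734 and 234. The 277 genes changed at least 2-fold became 653 without cured replicate 2, 183 without cured replicate 1 and 182 without cured replicate 3.

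The calls were also compared over 9 settings, namely 6 scalings, 2 background corrections and the series table, a comparison added after the data were seen. In every one of the 9 settings, 483 outside genes were higher in the cured strain and 31 were lower. Without the spike-in scaling, 226 were lower in each of the others. Between these settings, 713 of the 4824 outside genes were called in opposite directions.

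**Figure D3:**
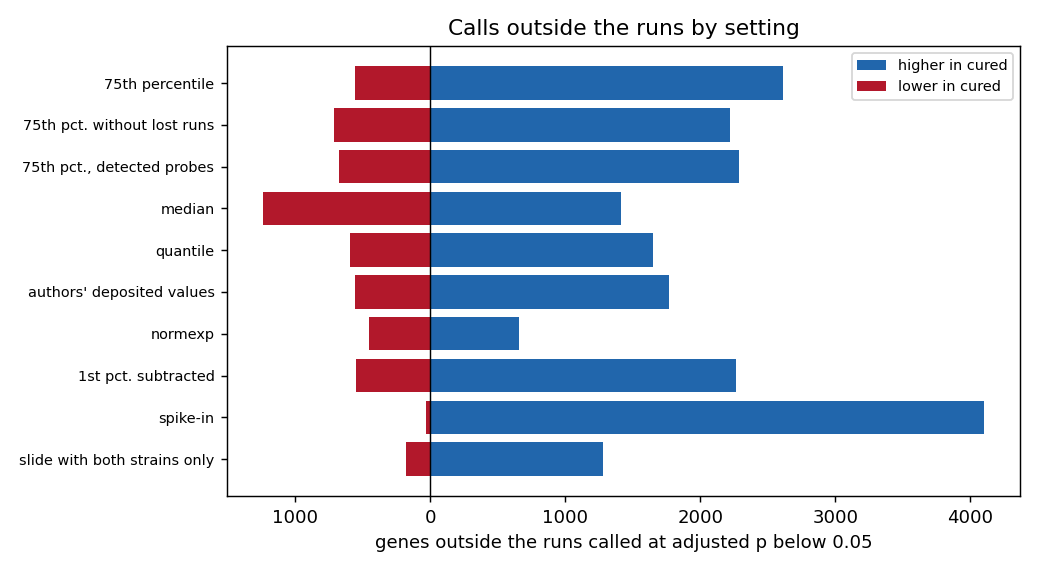
Number of outside genes called higher (right, blue) and lower (left, red) in the cured strain at a limma adjusted p below 0.05 (x axis), 1 bar pair per scaling, background correction, source of values or sample choice (y axis). The higher calls range from 658 with normexp to 4104 with spike-in scaling, against 2610 with the 75th percentile.

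The largest rises among outside genes were those of KTR9_RS08540 and KTR9_RS21450. KTR9_RS21450 rose by 1.92 on the log2 scale, or 3.79-fold (limma adjusted p = 0.000902), which is 1.55 above the outside median, and it passed in all 9 settings. Its cured arrays stood at 0.70, 2.18 and 0.57 on the log2 scale relative to the 75th percentile. Its difference was 1.41 without cured replicate 2, 2.69 with spike-in scaling and 2.97 on slide 3, where replicate 2 is the cured array. KTR9_RS08540 rose by 1.99, or 3.97-fold (limma adjusted p = 0.0116), but its cured arrays stood at 2.23, -0.81 and 0.63 on the same scale, and it passed in 5 of the 9 settings. Its difference was 1.22 without cured replicate 1 and 2.74 without cured replicate 2. With slide as a fixed block it was 0.62, which did not pass.

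The largest falls were those of KTR9_RS18880 and KTR9_RS24840. KTR9_RS18880 was 7.07-fold lower, a log2 difference of -2.82 (limma adjusted p = 0.00043), with -1.30 under quantile normalization, where it did not pass. Its wild-type arrays stood at 11.2, 11.3 and 9.41, and the difference was -3.42 without wild-type replicate 3. It was -1.92 on slide 3, -2.05 with spike-in scaling and -1.05 with the series table. KTR9_RS18880 had a strong signal, with a wild-type mean of 10.6 on the log2 scale after scaling. Signals on the cured arrays were compressed, and power-law fits against wild-type level had powers from 0.667 to 0.824. A fall in a gene this strong can therefore come with its signal level alone. Whether the fall of KTR9_RS18880 exceeds that was not tested. KTR9_RS24840 was 5.39-fold lower, a log2 difference of -2.43 (limma adjusted p = 1.29e-06), and it passed in all 9 settings, with -1.66 under spike-in scaling.

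KTR9_RS24840 opened a stretch of 6 neighbours, numbered 24840 to 24865, that fell together, with a median of -2.14 on the log2 scale and a range from -2.43 to -1.52. The highest limma adjusted p in the stretch was 1.23e-05, and its median was -1.91 with quantile normalization and -1.38 with spike-in scaling. The stretch was picked by its calls on these same arrays, so the p and the quantile value are no separate support. It holds the short low stretch of 5 genes, numbered 24840 to 24860, that had been left among the outside genes. The longest stretch that fell held 8 genes, numbered 19185 to 19220, with a median of -1.16, or -1.29 with quantile normalization and -0.39 with spike-in scaling. The stretch that rose most held 4 genes, numbered 7835 to 7850, with a median of 1.21, which is 0.84 above the outside median.

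In all, 5 stretches of at least 4 neighbours fell and 5 rose in each of the 9 settings other than spike-in scaling. With spike-in scaling, the medians of 2 of the falling stretches were -0.056 and 0.084, so one was near 0 and the other turned. In 1000 shuffled orders of the outside genes, falling stretches averaged 0.028 with at most 1, and rising stretches averaged 0.451 with at most 4. The longest falling stretch held 8 genes against at most 4 in shuffled orders, but the longest rising one held 4, and shuffled orders reached 6. Shuffled orders treat neighbours as independent, but rank correlations between the signal levels of neighbouring outside genes were 0.24 to 0.41 within the arrays. Whether the strain differences of neighbours vary together was not tested. The shuffles therefore cannot tell a strain effect on a stretch from neighbours that vary together.

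Signals of the outside genes before scaling were higher on the cured arrays, least so among strong signals. The 1st percentile of the outside genes before scaling was 34.5 ± 7.45 (SD, n = 3) on the cured arrays and 11.3 ± 2.78 (SD, n = 3) on the wild-type arrays, an exact two-sided permutation p of 0.1. The ratio of these means was 3.06, against 2.67 for the median and 1.39 for the 95th percentile. The interquartile range of the outside genes on the log2 scale was 1.09 ± 0.139 (SD, n = 3) and 1.62 ± 0.086 (SD, n = 3), with the same exact p of 0.1. Cured replicate 2 lay between the other cured arrays and the wild type, with a 1st percentile of 26.0 and an interquartile range of 1.25. On cured arrays 1 to 3, differences of outside genes from the wild-type mean had Spearman correlations of -0.77, -0.65 and -0.77 with that mean. The wild-type mean enters both sides, which by itself lowers these correlations. Scaling that shifts whole arrays leaves them unchanged, so with median scaling too, the direction of calls went partly with signal level.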

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

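Spike-in scaling, the 75th percentile without the lost runs, normexp on median signals and subtraction of the 1st percentile were chosen after the data were seen; normexp was planned on mean signals, which were not used here. Runs 1 and 2 were lower and run 3 was higher in all 24 alternatives, with 133 to 156 genes called in run 3. With probes above background on all 6 arrays, 14 genes of each lost run were called, since only 14 of each were tested. The log2 rise of run 3 over the outside genes became 1.98 with quantile normalization, 2.27 with the series table, 2.13 with the 1st percentile subtracted, 1.48 with probes above background on all 6 arrays and 0.62 with normexp, and 1.49 to 1.64 with 1 replicate left out. Outside genes higher in the cured strain numbered 1648 with quantile normalization, 1412 with median scaling, 4104 with spike-in scaling, 658 with normexp, 1734 with slide as a fixed block and 1281 on slide 3 alone. Those lower numbered 1239 with median scaling, 34 with spike-in scaling, 234 with the slide block and 179 on slide 3 alone. Genes changed at least 2-fold numbered 177 without the lost runs in the scaling, 2877 with spike-in scaling, 36 with normexp, 762 with the 1st percentile subtracted, 121 with slide as a random block, 73 with slide as a fixed block, 73 on slide 3 alone and 182 to 653 with 1 replicate left out. The cause was not tested for these. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at 0.31, -0.42 and -0.41 across genes, not every array correlated best with its own number, and the replicate block gave 2406 higher and 505 lower. KTR9_RS08540 kept its direction but not its call in 9 of 24 alternatives and KTR9_RS18880 in 1 of 24. Gene set tests (camera, fry) and scaling without pGKT2 probes were not run. Signals near background limit the lost genes to bounds.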

Other observations

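All tests in this part were chosen after the results were seen. The last locus tags, numbered above run 3, repeated the order of the rest. The 7 genes numbered 26415 to 26445 were low, the 34 genes numbered 26450 to 26615 were not set apart from the outside genes, the 4 genes numbered 26620 to 26635 were low and the 7 genes numbered 26640 to 26670 were high. Of the 11 low genes, all were called lower by limma and 10 were well above background on every wild-type array and on no cured array, with a median bound of at least 41.6-fold lower. That bound also holds only for the percentile scaling. All 7 high genes were called higher, with a median difference of 2.01 on the log2 scale.

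The loss of run 2 beside run 1 is one pattern, since the labels name 1 cured plasmid. Hybridisation of a strain with widely different gene content is argued against, since 10 of the 5003 genes beyond runs 1 and 2 were lost, all 10 in the low stretches of the last locus tags. Whether both runs are parts of 1 replicon cannot be told apart from 2 replicons without a replicon table, although 34 outside genes lay between both low stretches of the last locus tags. Genes of run 2 that were present but not transcribed also stay open, because RNA signals do not measure DNA; 2 outside genes were not well above background on any cured array, and neither was on a wild-type array. The strain is known to carry other plasmids, and loss of one of them together with pGKT2 is a hypothesis that sequencing of the cured strain could test.

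The rise of run 3 over the outside genes is another pattern, which a scaling that shifts a whole array leaves unchanged by construction. In the 4 settings of scaling, background correction or source of values that could change it, the rise was 0.62 on the log2 scale with normexp and 1.98 to 2.27 in the others. The normexp value also holds the effect of its offset and is not used as evidence. Quantile normalization, the series table and subtraction of the 1st percentile did not reduce the rise, so it did not rest on the main scaling alone. For the raised signal of weak genes, run 3 exceeded outside genes of like wild-type signal by a median of at least 1.204 on each cured array. Outside genes that weak therefore rose less than run 3. Run 3 was chosen by its rise on these same arrays, which favours such an excess, so no conclusion about this cause is drawn. More copies of run 3 would raise nearly all its genes, and 97.5% lay above such outside genes, a share that the choice of run 3 also favours. The interquartile range of run 3, 0.60, was wider than the 0.36 of the outside genes. A change in copies, a change in regulation and an added signal on the cured arrays that differs between probes cannot be told apart here. Matching on wild-type signal does not test such an added signal. Measurement of DNA may follow this up.

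The raised weak and middling signals on the cured arrays are another pattern. Optical or non-specific background is argued against, since the 1st percentile of the outside genes was at least 7.77 times the median signal of either lost run on any cured array. The slide cannot be told apart from the strain, since only cured replicate 2 shared a slide with the wild type; its 1st percentile was 1.81 times the higher of both. A near-constant signal added to every gene present, as carried-over DNA might give, left residual SDs 0.719 to 0.851 times those of scaling alone, which has fewer parameters. Against a power law with as many parameters, tried next, its residual SDs were higher, by up to 1.13 times, which argues against a strictly constant signal. An added signal that differs between probes, and a difference in growth state between the strains, were not tested.

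The real split of the 6 arrays called 3170 outside genes and the highest of the other splits called 0, so 1 of 10 splits reached the real count. With 10 splits, the share cannot fall below 0.1, which is too few for a share under 0.05. Each of the other splits also mixes both strains in both groups. Differences between strains then enter the residual spread, which keeps calls low, so no conclusion about chance is drawn from this contrast.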
